A study of Mus musculus with 9 samples.

How the data were processed

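Messenger RNA levels were measured in 3 brain regions of male C57BL/6J mice on 3 feeding regimens, with 9 single-colour (Cy3) Agilent whole mouse genome arrays. Each array held RNA pooled from 4 mice on day 8, of which 400 ng was labelled, so each region and diet has a single array and no replicates. The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction. Their processed signal is an intensity, background-subtracted and detrended within 1 array and not scaled between arrays, and the deposited median spot and local background signals are intensities as well. The deposited quality columns are of another kind (other than a measurement), flags of 0 or 1 that mark spots well above background, saturated spots and outliers. The authors also deposited a table of values that are a ratio. It was tested against the scanner files: in each region, 99.2% to 99.3% of the values lay within 0.01 log2 units of the ratio of processed signal to the region's AD array after multiplication by 1 constant per array. The authors' constants differed from those of the scaling used here by 0.005 to 0.131 log2 units.

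The log2 processed signal of each spot was taken relative to the 75th percentile of the 43379 noncontrol spots of its array. Outlier spots were left out, and spots of the same probe were averaged. Probes were named through the RefSeq accession given in the files, matched to the symbols of a mouse gene table (assembly GRCm38.p6), which was used for names alone. Of 41174 probes, 22944 matched a symbol and 18230 did not, giving 16355 genes. For a gene with several probes, the probe with the highest mean over the 9 arrays was used. Between 59.8% and 69.6% of the noncontrol spots of an array were well above background, and the SD of log2 signal between the spots of a probe printed 10 times was 0.075 to 0.123. The number of arrays limits the precision.

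Regions, and diets over the 3 regions, were compared with limma 3.58.1 in R 4.3.3, with the model region plus diet, 4 residual degrees of freedom and Benjamini-Hochberg adjustment per contrast at 0.05. A gene was fitted if it was well above background on at least 3 arrays and had a value on at least 6. The 3 regions of a diet come from the same pool of mice, so p-values for diets are too small. Within a region no test was possible, and genes that were well above background on both arrays were counted at a difference of at least 1 log2 unit. Fold bounds for genes that some array of the dim group does not show well above background use, on each such array, the larger of the gene's own value and the lowest well-above-background signal. The fit was tested on simulated data. For RFR against AD with 12532 genes, it recovered 24%, 52%, 86% and 96% of genes changed 1.41-fold, 2-fold, 4-fold and 16-fold, with 3 of 12332 unchanged genes called. For amygdala against hypothalamus the shares were 18%, 62%, 92% and 100%, again with 3 of 12332 unchanged genes called. The simulated noise was independent between arrays, with no effect shared by the arrays of a pool or slide. These shares and false calls therefore do not hold for the diet contrasts of the data, where the 3 arrays of a diet share a pool.

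In each contrast, 34 gene lists (feeding, stress, metabolism, transmitters, brain cell types and neighbouring tissue) were described by the median log2 difference of the measured members relative to the median of all genes. Its percentile was taken among 10000 random lists of the same size, matched on expression in 20 bins, for lists with at least 3 measured members. A list outside the 2.5th to 97.5th percentile is called outside the random range, which 5% of random lists are. Random lists draw genes independently, so lists whose members vary together between arrays can fall outside more often with no diet effect. There were 408 combinations of list and contrast. On simulated values of the amygdala contrast of CR with AD, 3, 92 and 100 of 100 lists of 15 genes fell outside at shifts of 0, 0.5 and 1 log2 units.

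Contrasts, tests, lists and the rule for naming genes were chosen before the data were examined. Within a region, only genes well above background on both arrays were ranked. Named are the 5 of these with the largest difference in each direction for CR or RFR against AD, and 3 for CR against RFR. Named too are up to 10 in each direction past the threshold in the limma fit of a diet with 1 direction in all regions, the 5 highest in each region against both others, and up to 4 members of a list. Alternatives changed the background correction (normexp with an offset of 50), the scaling (quantile), the source (the authors' table), the filter, the probe choice, the variance model and the treatment of slides, and left out each region or each diet pool in turn. The normexp alternative was planned on mean spot signals and was run on the median spot signals that the files hold. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the rest. The arrays lay on 3 slides. Slide 1 held the 3 AD arrays and the prefrontal cortex RFR array, slide 2 the remaining arrays except the amygdala CR array, which was alone on slide 3 and scanned 57 days later. Lists of bone and marrow neutrophil genes and the fits with slide as a fixed term and without the amygdala CR array were added after seeing the data. Probes with no matched symbol were left out of the comparisons and fitted separately.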

Results

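Gene expression was measured in amygdala, hypothalamus and prefrontal cortex of mice with free access to food (AD), with restricted food (CR) or with alternating fasting and refeeding (RFR). The CR mice were given a fixed part of the food that the RFR mice ate. Each of the 9 combinations of region and diet has 1 array of RNA pooled from 4 mice on day 8, with no replicates. Between 25958 and 30199 of the 43379 noncontrol spots of an array were well above background. Values are log2 processed signal relative to the 75th percentile of the array. The series title asks how food restriction relates to gene expression in the amygdala of mice tested for anxiety- and depression-like behaviour.

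The region comparison asked which genes were highest in each dissected region. The 5 genes named per region were picked by size from these same data, so known markers were not tested. Hypothalamus stood out by its neuropeptides: Hcrt, which encodes the orexins, was 355-fold higher than in amygdala and 1200-fold higher than in prefrontal cortex. Pmch, the precursor of melanin-concentrating hormone, was 292-fold and 1200-fold higher, and Oxt, the oxytocin precursor, 63.5-fold and 844-fold higher. Agrp, a peptide of hunger-driving neurons, was at least 62.1-fold higher than in amygdala and at least 77.3-fold higher than in prefrontal cortex, and the transcription factor Hmx3 at least 87.2-fold and 74.3-fold. Among the genes highest in amygdala was Cyp26b1, a retinoic acid-degrading enzyme. It was 53.6-fold higher than in hypothalamus and 11.3-fold higher than in prefrontal cortex. Tfap2c was at least 7.34-fold and 7.84-fold higher in amygdala than in those regions, Ano2 at least 7.78-fold and 11.9-fold, Mab21l1 at least 5.44-fold and 7.0-fold, and Alox12e at least 4.3-fold and 5.53-fold. Among the genes highest in prefrontal cortex was Ovol2, 14.7-fold higher than in amygdala and 40.6-fold higher than in hypothalamus. Helt was at least 8.97-fold and 4.14-fold higher there, Cryba2 at least 4.65-fold and 3.07-fold, Ocm at least 4.17-fold and 2.76-fold, and Serpinb8 at least 4.13-fold and 2.73-fold. All of these genes passed the limma test in both contrasts of their region, with 3 arrays per region, which the choice of genes required.

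By limma, 6053 of 12619 genes differed between hypothalamus and prefrontal cortex, 3370 of them higher in hypothalamus. Between amygdala and hypothalamus 3717 genes differed (1707 higher in amygdala), and between amygdala and prefrontal cortex 2815 (1532 higher in amygdala). Without the RFR pool these 3 contrasts gave 3492, 1428 and 892 genes, without the CR pool 4739, 2238 and 1564, and with slide as a fixed term the last gave 1390. Against both other regions, 1749 genes were higher in hypothalamus, 1093 in prefrontal cortex and 223 in amygdala.

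The comparison of diets over the 3 regions asked which genes responded alike in all of them. Prl (NM_011164) and Gh (NM_008117), which encode the pituitary hormones prolactin and growth hormone, were well above background on all 3 RFR arrays and on none of the other 6. Prl was at least 11.3-fold higher on RFR than AD arrays and at least 12.7-fold higher than on CR arrays. Gh was at least 3.36-fold higher than on AD arrays and at least 3.76-fold higher than on CR arrays. Pomc, the precursor of corticotropin and melanocortins, differed in sign between regions: RFR minus AD was 1.55 in amygdala, 0.82 in prefrontal cortex and -0.82 in hypothalamus.

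In the limma fit, Prl and Gh were the 2 genes past the threshold in RFR against AD, both higher in 3 of 3 regions, and the 2 genes past it in CR against RFR, both lower in 3 of 3 regions. For Prl, RFR minus AD was 5.63 ± 0.26 (SE; adjusted p = 0.0018, 3.7e-05 to 0.21 over the alternatives), and CR minus RFR was -5.88 ± 0.26 (adjusted p = 0.0014, 3.6e-05 to 0.2). For Gh, RFR minus AD was 3.82 ± 0.27 (adjusted p = 0.015, 0.015 to 1.0 over the alternatives), and CR minus RFR was -3.85 ± 0.27 (adjusted p = 0.014, 0.0034 to 0.37). The fitted differences depend on values near background, so the bounds above, on the processed signal, are the folds to read. Under normexp, whose offset compresses dim signals, the Prl differences were 2.16 and -2.67, below those bounds, and with every dim value raised to its array's floor they were 3.5 and -3.67 (Gh 1.75 and -1.91). At an unadjusted p under 0.05 there were 775 genes in RFR against AD and 1865 in CR against RFR. With slide as a fixed term, which leaves fewer residual degrees of freedom, the Prl differences were 5.56 and -5.64 and those of Gh 3.66 and -4.01, and all 4 calls ended. They ended too with no filter on dim genes, and those of Gh ended without amygdala, without prefrontal cortex and without the amygdala CR array, with differences about as large (3.41, 3.85 and 3.82 for RFR minus AD, -3.7, -3.94 and -3.91 for CR minus RFR). Under normexp the Gh call in RFR against AD ended (0.87). Over the alternatives, 0 to 13 genes were past the threshold in RFR against AD, the 13 with slide as a fixed term. All these p-values are too small, because the 3 regions of a diet come from the same pool of mice.

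For CR against AD, limma called 0 of 12619 genes, with 2082 at an unadjusted p under 0.05. Without amygdala, limma called 1231 genes, 656 higher and 575 lower, in a fit with 2 residual degrees of freedom. In that fit both CR arrays lay on slide 2 and both AD arrays on slide 1, so slide and diet cannot be told apart for these genes. Slc4a7, a sodium bicarbonate cotransporter, was 1.95 higher on the CR array in hypothalamus and 1.75 in prefrontal cortex, but -3.95 in amygdala. Clec2d differed by 1.67, 1.27 and 0.01 in the same order, Arid5b by -1.53, -1.78 and -0.34, and the aminopeptidase Lnpep by -1.3, -1.61 and -0.33. These 4 genes were chosen after their values were seen. The p-values behind these counts are too small, for the reason given above. The authors' table gave 3 genes and slide as a fixed term 5. For CR against RFR, the count was 41 with normexp, 41 with trended and robust variances, 24 with genes well above background on all arrays, 21 from the authors' table, and 0 with slide as a fixed term or with no filter.

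**Figure D1:**
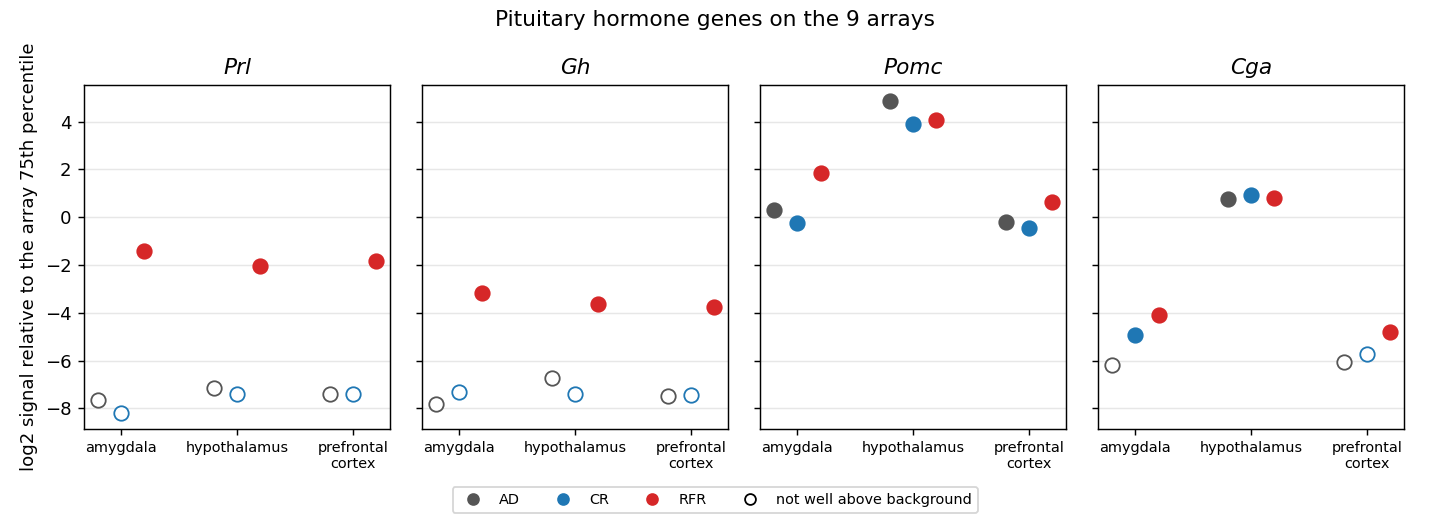
Log2 signal of 4 pituitary hormone genes on each of the 9 arrays, relative to the 75th percentile of the array; colours give the diet and open circles mark arrays on which the gene was not well above background. Prl lies between -2.04 and -1.43 on the 3 RFR arrays and is not well above background on the other 6.

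In the amygdala, the RFR array carried higher signal for choroid plexus genes than the AD array. All 10 measured members were higher, with a list median 0.82 above all genes, led by Calml4 (2.24), Kcne2 (1.94), Ttr, the thyroid hormone carrier (1.81), and the folate receptor Folr1 (1.48). Orexigenic peptides had a median 0.88 above all genes, 3 of 4 higher, with Pmch at 1.82, Hcrt at 1.26 and Npy at -0.23, and anorexigenic peptides one of 0.38, 6 of 8 higher, with Pomc at 1.55. In the list of hypothalamic neurons 13 of 14 members were higher. Pmch, Hcrt and Pomc belong to that list too, so these list results share genes. With 1 array per diet, neighbouring tissue in the dissection and a diet effect cannot be told apart. Of the single genes well above background on both arrays, which leaves out Prl and Gh, those with the largest differences were as follows. On the higher side they were Olfr611 (2.69), the cartilage matrix gene Comp (2.54), Mgarp (2.26), Calml4 (2.24) and Lgr5 (2.18). On the lower side they were Slc4a7 (-2.87), Dact2 (-2.7), the dopamine receptor Drd4 (-2.66), Shroom3 (-2.46) and Sec14l4 (-2.13). Of these, Mgarp was under 2-fold with normexp. Respiratory chain genes were lower, 18 of 22, with a median of -0.21 that fell inside the random range under normexp.

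The amygdala CR array differed from the AD array at 399 genes of at least 2-fold, against 177 for RFR and AD, for genes well above background on both arrays. Higher were Ldoc1 (3.11), the Myc-network repressor Mxd1 (2.7), Bpifb6 (2.54), Usp27x (2.33) and the histone demethylase Kdm4a (2.31). Ldoc1 (-5.25) and Bpifb6 (-5.17) were dim on the AD array and well above background on 5 of 9 arrays. Mxd1, Usp27x and Kdm4a were well above background on all 9. Lower were Slc4a7 (-3.95), Sec14l4 (-3.53), Tmem232 (-3.28), Shroom3 (-2.9) and Heg1 (-2.89). Tmem232 (-5.89) and Heg1 (-5.79) were dim on the CR array and well above background on 5 and 4 of 9 arrays. Oligodendrocyte genes had a median 0.33 above all genes, with Mog at 1.19 and 11 of 14 members higher. Also outside the random range were neurons (0.18, 6 of 12 higher), glycolysis (0.06, 9 of 19 higher) and hippocampal neurons (-0.38, 3 of 5 lower, inside under normexp and quantile scaling). Choroid plexus, orexigenic and anorexigenic lists lay inside the random range, with medians of -0.03, -0.2 and -0.19. Against the RFR array, choroid plexus genes were lower on the CR array (-0.54, 11 of 11). Ependymal genes (-0.45, 7 of 7) and hypothalamic neurons (-0.29, 10 of 14) were lower too. Oligodendrocyte genes (0.46, 14 of 14), blood genes (0.92, 4 of 4) and striatal projection neurons (0.36, 11 of 12) were higher. The largest differences there, for genes well above background on both arrays, were Vangl1 (2.62), Ldoc1 (2.53) and Bpifb6 (2.45) higher and Tas2r140 (-3.27), H1f1 (-3.24) and Comp (-3.18) lower. Tas2r140 was dim on the CR array (-5.27) and well above background on 3 of 9 arrays. Bpifb6 was under 2-fold with normexp in CR minus AD.

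Of the 399 genes in amygdala CR minus AD, 68.4% were higher, 88.2% from the authors' table and 54.9% under normexp. Of the 177 genes in RFR minus AD, 67.8% were higher (52.8% under quantile scaling and 78.0% from the authors' table), and of the 264 in CR minus RFR, 39.4% were (27.8% under normexp and 56.0% from the authors' table). Genes well above background on only 1 array and at least 2-fold by their bounds came on top. In the order of these contrasts, 98, 86 and 54 were on the first array named and 79, 44 and 88 on the second. The median of all genes in amygdala CR minus AD was -0.11, and 0.015 from the authors' table. In hypothalamus it was -0.032 and 0.091, and in prefrontal cortex -0.026 and 0.077, so list medians are given relative to all genes. The amygdala CR array was alone on its slide and scan, so for its contrasts batch and diet cannot be told apart.

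In the hypothalamus, feeding peptides differed by less than 2-fold. On the CR array Pomc was lower than on the AD array (-0.97), and Pmch (0.52), Npy (0.35) and Hcrt (0.27) were higher, but orexigenic Gal was lower (-0.52) and anorexigenic Ucn3 (0.53) and Nmb (0.36) were higher. The orexigenic list median of 0.3 and the anorexigenic one of -0.04 lay inside the random range. On the RFR array Pomc (-0.82), Gal (-0.5) and Hcrt (-0.3) were lower and Ucn3 (0.8) and Agrp (0.37) higher than on the AD array, with an orexigenic median of -0.07 and an anorexigenic one of 0. Genes of sterol and fatty acid synthesis were lower in CR, 15 of 18, with a median of -0.28, led by Mvd (-0.94) of the mevalonate pathway. They were lower in RFR too, 17 of 18 (-0.15, inside the random range under normexp), beside oligodendrocyte genes, 13 of 14 (-0.29), and microglia genes, 9 of 10 (-0.13, inside the range under quantile scaling and with the mean of all probes). Meningeal and fibroblast genes were higher on the CR array, 12 of 12, with a median of 0.66, led by Slc22a6 (2.17), Ogn (1.64) and Ptgds (1.31), and endothelial and mural cell genes were higher beside them, 10 of 14 (0.27, inside the random range under normexp). Choroid plexus genes lay inside the random range in CR (0.11) and RFR (-0.03).

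Single genes are ranked here among those well above background on both arrays. The largest differences in hypothalamus CR minus AD were Cd300lg (2.75), Acss3 (2.57), Sh2b2 (2.43), the organic anion transporter Slc22a6 (2.17) and the phosphatase Ptpn4 (2.08). On the lower side they were Shroom3 (-3.12), the activin receptor Acvr1b (-2.95), Olfr1441 (-2.5), Rhox5 (-2.5) and Rab5b (-2.28). In RFR minus AD, Sh2b2 (2.64), Acvr1b (-2.87), Shroom3 (-2.45) and Rab5b (-2.34) differed the same way, beside Impg2 (2.75), Gas2 (2.55), Ppm1j (2.26), Prkch (2.15), Bach1 (-2.19) and Stoml3 (-2.15). Both contrasts use the same AD array, which stood apart from all other arrays at Acvr1b (-1.51 against -4.58 to -3.37), Rab5b (-1.33 against -4.35 to -3.36) and Sh2b2 (-4.13 against -2.31 to -1.1). The same direction in both diets is thus not separate support. Shroom3 was higher on the AD array in every region. The CR and RFR arrays, both on slide 2, differed most, in this ranking, at Ptpn4 (2.76), Gjd3 (2.29) and the globin gene Hba-a1 (1.97), higher in CR, and at Socs7 (-2.69), Impg2 (-2.67) and Fbn2 (-2.47), lower. Under normexp Cd300lg in CR minus AD and Ppm1j in RFR minus AD were under 2-fold, and Impg2 in CR minus RFR was with the mean of all probes. Counts of at least 2-fold, for genes well above background on both arrays, were 159 for CR minus AD, 81 for RFR minus AD and 62 for CR minus RFR. For the first, 48.4% were higher, 75.9% from the authors' table and 35.2% under normexp. For the second, 40.7% were higher, 53.7% from the authors' table and 30.3% under normexp. Genes well above background on only 1 array and at least 2-fold by their bounds came on top. In the order of the 3 contrasts, 77, 41 and 77 were on the first array named and 75, 68 and 42 on the second.

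In the prefrontal cortex, bone and matrix genes were lower on both restricted-diet arrays than on the AD array. In CR minus AD these were Bglap3, an osteocalcin gene (-3.06), and Col1a1, type I collagen (-2.49), and in RFR minus AD Bglap, osteocalcin itself (-4.07). All 12 meningeal and fibroblast genes were lower in CR (median -0.58), and 9 of 12 in RFR (-0.28). Genes of sterol and fatty acid synthesis were lower in CR, 13 of 17 (-0.18), and in RFR, 16 of 18 (-0.25), with Mvd at -0.84 and -0.6. Cell type lists were lower beside it in RFR, oligodendrocytes by -0.26 (11 of 13), neurons by -0.19 (9 of 12), microglia by -0.16 (8 of 11), astrocytes by -0.14 (inside the range under normexp) and endothelial cells by -0.15 (inside it under normexp, in the authors' table and with the mean of all probes), and in CR astrocytes were lower (-0.19) and oligodendrocytes higher (0.29). Immediate early genes of neuronal activity were higher on the RFR array, 14 of 19 (0.3), with Egr2 at 0.57 and Egr1 at 0.53. Feeding receptors were lower on the CR array, 6 of 9, with a median of -0.45 and the cannabinoid receptor Cnr1 at -1.32, while Npy1r was higher (0.84). Orexigenic medians were 0.22 in CR and 0.02 in RFR, anorexigenic ones -0.11 and 0.12, all inside the random range. Choroid plexus genes had 0.38 in CR, from 5 members and inside the range under normexp and quantile scaling, and 0.21 in RFR.

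Further genes with large differences in prefrontal cortex CR minus AD were Dpt (2.82), Tex19.2 (2.61), Tcerg1l (2.43), Prrg4 (2.12) and the synaptic gene Rims3 (2.08), and Upb1 (-2.45), Chil3 (-2.37) and the Wnt antagonist Dkk2 (-2.29). Of these, Prrg4 and Rims3 were under 2-fold with normexp. In RFR minus AD, both arrays on slide 1, they were Efna4 (2.03), Cd300lg (1.92), Pp2d1 (1.87), Zic4 (1.77) and Vps72 (1.75), each under 2-fold with normexp. On the lower side of RFR minus AD they were Ugt2a3 (-3.53), the serotonin receptor Htr5b (-3.53), the water channel Aqp8 (-3.39) and Otop3 (-3.36). CR minus RFR was led by Cenpi (3.88), Muc15 (2.77) and Ireb2 (2.61), and by Mcf2 (-2.44), Cd300lg (-2.4) and Zic4 (-2.25), of which Ireb2 and Cd300lg were under 2-fold with the mean of all probes. Counts of at least 2-fold, for genes well above background on both arrays, were 133 for CR minus AD, 115 for RFR minus AD and 97 for CR minus RFR. The shares higher were 38.3%, 21.7% and 58.8%, against 59.7%, 14.8% and 81.0% from the authors' table and 25.0%, 11.1% and 40.6% under normexp. Genes well above background on only 1 array and at least 2-fold by their bounds came on top. In the same order of contrasts, 65, 58 and 96 were on the first array named and 75, 103 and 56 on the second.

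**Figure D2:**
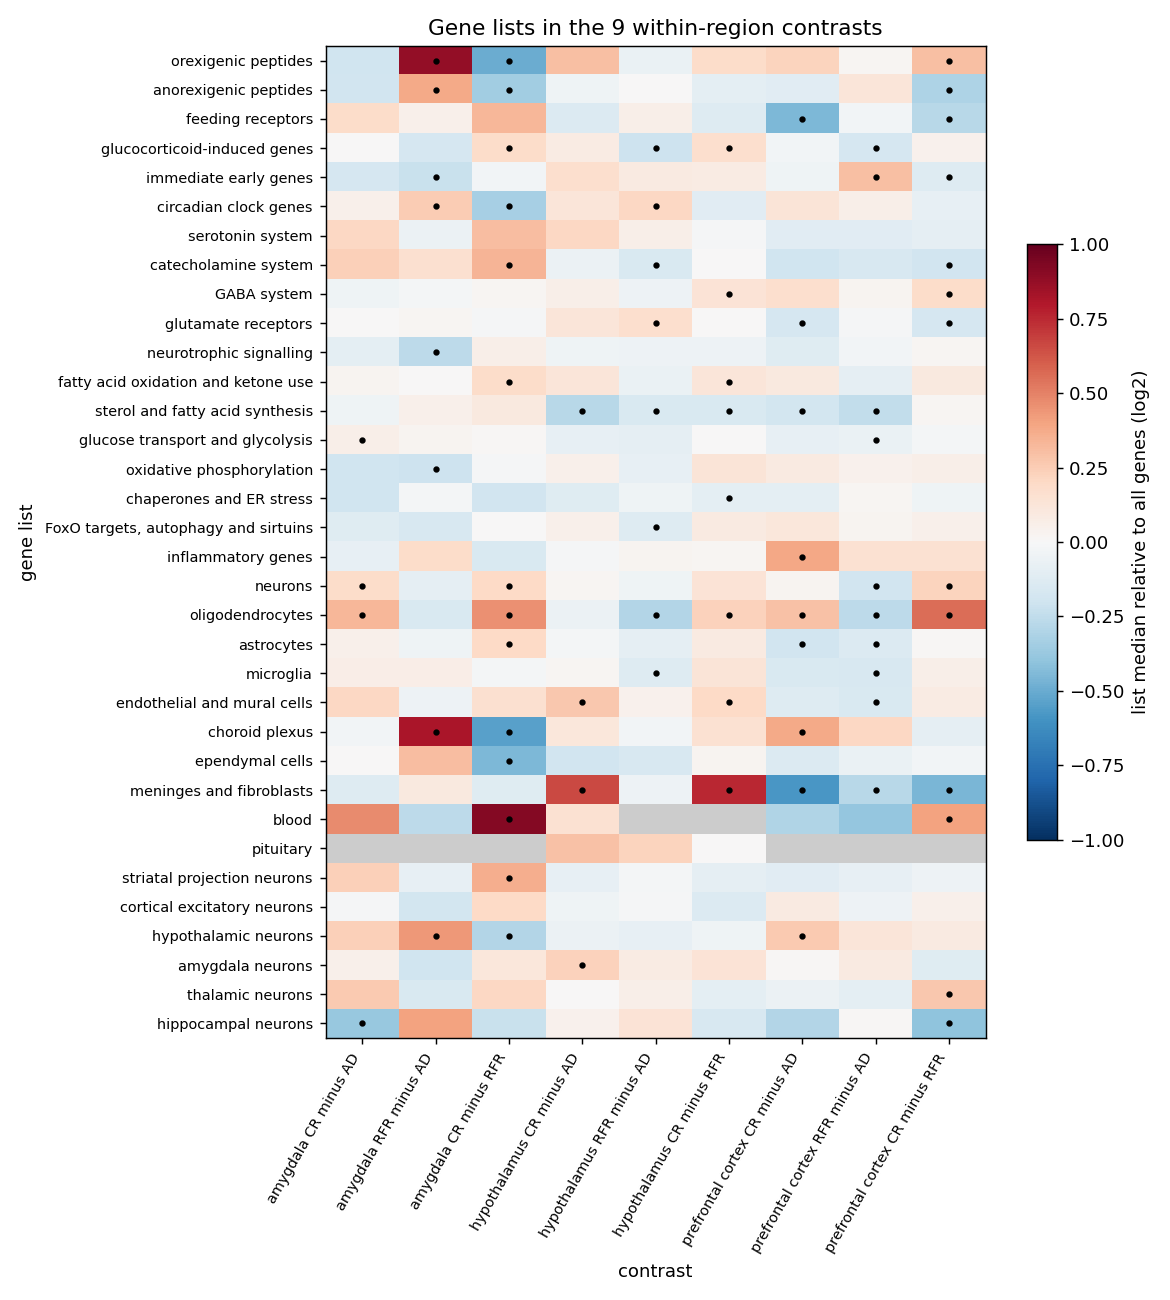
Median log2 difference of each of the 34 gene lists relative to all genes in the 9 within-region contrasts; colour gives the median, black dots mark lists outside the random range and grey cells lists with under 3 measured members. Choroid plexus genes stand 0.82 above all genes in amygdala RFR minus AD, and meningeal genes 0.66 above in hypothalamus CR minus AD and -0.58 in prefrontal cortex CR minus AD.

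The last comparison asked whether the diets, and the regions, shared their differences from AD. In the hypothalamus 37 genes were at least 2-fold lower than AD on both the CR and the RFR array, Shroom3, Acvr1b and Rab5b among them, and 6 were higher on both. In prefrontal cortex 42 genes were lower in both and 2 higher. In amygdala 25 were lower in both, Slc4a7, Sec14l4 and Shroom3 among them, and 43 higher. Under normexp the lower overlaps were 20, 13 and 15 in these regions and the higher ones 2, 1 and 14. Independent sets would give 0.08 to 2.58 genes, which is not the value for no effect, as the contrasts share an array. Of the gene lists, 4, 8 and 14 were outside the random range in amygdala for CR minus AD, RFR minus AD and CR minus RFR, 4, 8 and 8 in hypothalamus and 9, 10 and 13 in prefrontal cortex. The 5% of random lists is not the share for no effect, since members of a list can vary together and lists share genes. The diets share the AD array of their region, which raises such overlaps and correlations by itself. In hypothalamus the CR and RFR arrays also lay on slide 2 and the AD array on slide 1, so slide and diet cannot be told apart there. Across genes, which are not independent replicates, r of CR minus AD with RFR minus AD was 0.53 in amygdala, 0.64 in hypothalamus and 0.57 in prefrontal cortex. Independent noise with a shared array gave 0.53, 0.49 and 0.49, from 1 simulated draw per region. That noise had the residual spread of the region plus diet model, which also holds any diet difference particular to 1 region. Subtracting the simulated covariance can therefore remove such differences too. The covariance less the simulated one had another order, 0.022, 0.007 and 0.004, so neither it nor r ranks the regions.

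Between regions, which share no array, CR minus AD in hypothalamus and prefrontal cortex had r = 0.66 across genes (0.77 under normexp), with 12 genes at least 2-fold higher in both (0.25 expected) and 20 lower (0.4 expected). These expected counts are for independent sets and are not the values for no effect, since both regions come from the same pools and both contrasts run from slide 1 to slide 2. RFR minus AD gave r = 0.45 for these regions. Amygdala gave -0.06 and -0.11 with hypothalamus and prefrontal cortex for CR minus AD, and -0.05 and -0.14 for RFR minus AD. CR minus AD of 1 region was also set against RFR minus AD of another. Hypothalamus and prefrontal cortex then gave 0.38 and 0.43. Amygdala CR minus AD gave -0.06 with hypothalamus and -0.32 with prefrontal cortex. Amygdala RFR minus AD gave -0.29 and -0.3 with the same regions. In CR minus RFR, which leaves the AD arrays out, amygdala gave 0.27 and 0.41, and hypothalamus and prefrontal cortex 0.44 (0.59 under normexp).

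**Figure D3:**
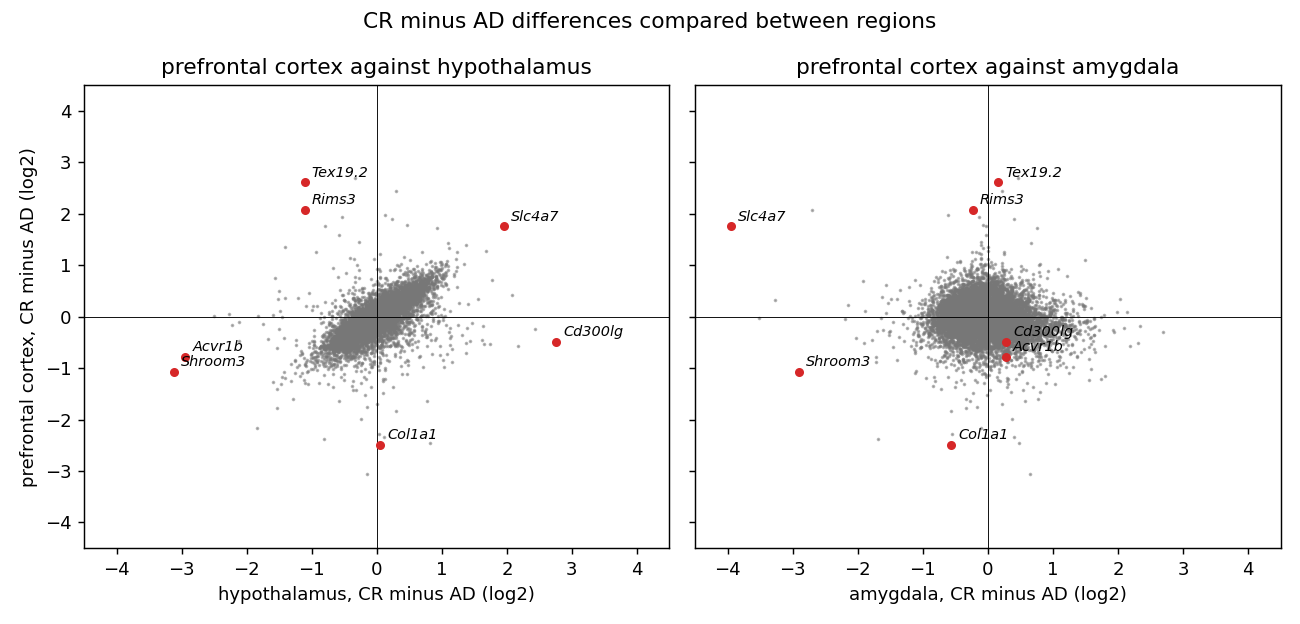
CR minus AD (log2) of each gene in prefrontal cortex against hypothalamus (left) and against amygdala (right), for genes well above background on the arrays compared, with genes named in the text in red. The cloud follows the diagonal on the left (r = 0.66) and not on the right (r = -0.11).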

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

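All tests of explanations in this part, and the lists of bone and marrow neutrophil genes, were chosen after the result was seen; none of the differences between regions given here was tested.

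Prl and Gh were well above background on all 3 RFR arrays and on no other array; a difference between slides is argued against, since on slide 1 Prl on the prefrontal cortex RFR array was 3.4 log2 units above the lowest well-above-background signal of the AD array. Pituitary RNA in the RFR pools may be a source, but of the 8 other pituitary genes 0 were at least 2-fold higher on RFR than AD arrays in at least 2 regions when dim AD values are raised to the lowest well-above-background signal of their array, and with only 2 of the 8 well above background on all RFR arrays this decides nothing. Cga, which reaches 2-fold in 2 regions on its own values, goes with it in amygdala (-4.1 on the RFR array, -6.18 and not well above background on the AD array) and prefrontal cortex (-4.81 and -6.07), but it was also well above background on the amygdala CR array (-4.91) and is at a high level in hypothalamus on all diets (0.77 to 0.91), while Lhb, on 9 arrays, differed by 0.11, -0.14 and -0.29 between RFR and AD. By limma over the regions, 3 of 6 list members passed adjusted over the list alone, Prl, Gh and Cga (1.13, higher in 3 of 3 regions, from dim values on 2 of the 3 AD arrays), with p-values too small because the pools are shared. A response to refeeding stays open and untested, since each diet is 1 pool.

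The differences from AD ran parallel in hypothalamus and prefrontal cortex and not in amygdala. Slide as the whole cause is argued against for RFR minus AD, where the prefrontal cortex arrays lay on the same slide and r with hypothalamus was still 0.45. For CR minus AD it stays open, since both regions span the same slides; hypothalamus CR minus AD had r = 0.38 with the within-slide RFR minus AD of prefrontal cortex. For amygdala, an AD array that stands apart is a candidate explanation, since without the AD arrays the smaller r with another region was 0.27, although it was 0.17 under normexp, below the 0.2 set for this test. The slide of the amygdala CR array as the whole cause is argued against by RFR minus AD, with no array on that slide, which gave r = -0.05 with hypothalamus, while in CR minus AD batch and diet cannot be told apart. A regional difference in the response stays open and untested.

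Meningeal and fibroblast genes went in opposite directions in CR minus AD, with medians, here before the median of all genes is subtracted, of 0.63 in hypothalamus and -0.61 in prefrontal cortex, a gap of 1.24. Different amounts of meninges in the dissected tissue and a diet effect on these genes cannot be told apart, since both predict that the members go together, as all 12 did in each region (a smaller share of 1.0). Bone or marrow on the prefrontal cortex AD array is not decided by the bone genes, of which 2 of 9 (Bglap and Bglap3), a share of 0.22, were at least 2-fold lower in CR. Of marrow neutrophil genes, S100a9 (1.03 on the AD array, -0.18 on CR and -0.52 on RFR), Camp (-3.73, -5.46 and not well above background, and -5.17) and Ngp, well above background on that array alone, go with it. S100a8 (-0.58 in CR and -1.54 in RFR minus AD) and Mpo (-1.04 and -0.41) were lower there too, while Ltf was higher on the CR array (0.82). Chil3 (-1.32, -3.69 and -3.53) is not particular to that array. It was lower than AD in amygdala (-1.69 in CR, -1.6 in RFR) and hypothalamus (-0.82 and -0.95) as well. All of these explanations stay open.

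Slc4a7 had opposite directions in hypothalamus (1.95) and amygdala (-3.95) for CR minus AD, a gap of 5.9, and in hypothalamus (1.56) and amygdala (-2.87) for RFR minus AD, a gap of 4.43. Both gaps use the same AD arrays, so they are not separate results. Slc4a7 was 4.95 on the amygdala AD array, against 1.0 to 3.56 on all other arrays, with 1.61 on the hypothalamus AD array. Tex19.2 in CR minus AD was 2.61 in prefrontal cortex and -1.11 in hypothalamus, a gap of 3.72. Rims3 was 2.08 and -1.11 in the same regions, a gap of 3.19. Immediate early genes in RFR minus AD had medians, again before that subtraction, of 0.31 in prefrontal cortex and -0.25 in amygdala, a gap of 0.56, and the amygdala list fell inside the random range under quantile scaling. Among 9118 probes with no matched symbol, which no comparison used, limma placed 141 past the threshold in RFR against AD (138 higher) and 336 in CR against RFR (318 lower), close to its edge (smallest adjusted p 0.0469 and 0.0307), the 141 dimmer than the probes tested (median -3.26 against -2.29), with p-values too small for the reason of shared pools.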

How the results depend on the processing

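Fits with slide as a fixed term, and without the amygdala CR array, were chosen after seeing the data. Counts are taken as kept within 1.5 times, and correlations within 0.1. Under normexp r of hypothalamus with prefrontal cortex was 0.77 for CR minus AD and 0.59 for CR minus RFR. The authors' table gives ratios to the AD array of a region, so it cannot give region contrasts. The cause of the changes below was not tested except where the setting shows it. Under normexp, which compresses dim signals, 2-fold counts for CR minus AD, RFR minus AD and CR minus RFR were 142, 75 and 115 in amygdala, 71, 33 and 31 in hypothalamus and 56, 36 and 32 in prefrontal cortex. With no filter, which adds genes, RFR minus AD and CR minus RFR gave 309 and 416 in amygdala, and the 3 contrasts 313, 191 and 182 in hypothalamus and 273, 283 and 254 in prefrontal cortex. The stricter filter gave 73 for prefrontal cortex RFR minus AD, and mean probes gave 180 there and 162 for CR minus RFR. limma counts for CR against AD were 3 from the authors' table and 5 with slide fixed. For RFR against AD they were 1 under normexp, 4 from the authors' table, 0 with the stricter filter (which leaves Prl and Gh out, as they are on 3 arrays; 707 at an unadjusted p under 0.05), 0 with no filter (602), 13 with slide fixed and 1 without the amygdala CR array. For CR against RFR they were 41 under normexp, 21 from the authors' table, 24 with the stricter filter, 0 with no filter (1568 at an unadjusted p under 0.05), 41 with trended variances and 0 with slide fixed. Amygdala against prefrontal cortex gave 1390 with slide fixed. Leaving out a region gave 1 to 1231 for CR against AD (1231 without amygdala), 1 to 2 for RFR against AD and 1 to 2 for CR against RFR. Leaving out a pool gave 1428 to 2953 for amygdala against hypothalamus, 892 to 2339 for amygdala against prefrontal cortex and 3492 to 5225 for hypothalamus against prefrontal cortex. Lists outside the random range numbered 7 in amygdala CR minus AD and 5 in hypothalamus CR minus RFR with mean probes, and 3 in CR minus AD over the regions under normexp. Under normexp 2 list medians changed sign: blood in CR minus AD (-0.17) and inflammatory genes in RFR minus AD (-0.02), both over the regions. A single gene under its threshold is taken as moved if its difference changed sign, and as kept or passing if it held its direction. Of the other results, single genes and lists, 650 were kept under normexp, 66 fell below their threshold, 2 passed it and 19 moved. From the authors' table these were 608, 20, 4 and 3, with mean probes 690, 37, 2 and 10, and with quantile scaling 716 were kept, 16 fell below and 7 passed. Signal over background limits the dim genes: folds of Prl and Gh are bounds. Several large within-region differences have a dim signal, close to background, on 1 of the 2 arrays.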

Other observations

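All tests of explanations in this part, the counts of other splits, were written down after the result was seen. Over the 3 regions, oligodendrocyte genes were higher on CR than RFR arrays. All 14 members had a positive mean difference (median 0.43 above all genes), all 14 were higher in amygdala and in hypothalamus and all 13 measured in prefrontal cortex, with Cldn11 at 0.79, Aspa at 0.57 and Mbp at 0.48. Other cell type lists were outside the random range in this contrast: neurons (0.12), endothelial cells (0.14, inside under normexp and in the authors' table), choroid plexus (-0.28, inside in the authors' table and with mean probes) and ependymal cells (-0.21, inside with mean probes). By limma, 6 of 14 passed adjusted over the list alone and 0 over all genes, where 1865 genes had an unadjusted p under 0.05. Blood genes were higher on CR arrays by a median of 1.08, 5 of 5, with Hba-a1 at 1.38, and 2 of them passed adjusted over the list alone, although the animals were perfused. These p-values are too small, since the regions of a diet come from the same pool of mice.

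Glucocorticoid-induced genes were lower on RFR than AD arrays, 14 of 18, with a median of -0.14, led by Mt2 (-0.51), Mt1 (-0.47) and Sgk1 (-0.37); by limma 1 of 18 passed adjusted over the list alone and 0 over all genes (775 at an unadjusted p under 0.05). Cell type lists moved in the same contrast: oligodendrocytes (-0.18, 14 of 14), astrocytes (-0.2, 10 of 11), blood (-0.67, 5 of 5) and meninges (-0.09, inside the random range under normexp and with mean probes) were lower and choroid plexus was higher (0.42, 11 of 11). In CR minus RFR, 7 of 18 passed adjusted over the list alone and 0 over all genes (1865 at an unadjusted p under 0.05 in limma), with 10 members higher, Mt1 (0.91) and Sgk1 (0.57) among them, and 8 lower, Per1 (-0.61) among them. The list median of 0.12 fell inside the random range under normexp and quantile scaling. Circadian clock genes were higher on RFR than AD arrays, 14 of 17 (0.15), with Per2 at 0.43 and Per3 at 0.51, the latter mostly from amygdala (1.74), and by limma 0 of 17 passed over all genes or over the list alone (775 of all genes at an unadjusted p under 0.05). These p-values are too small for the same reason.

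Other splits of the same 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05, and the other splits mix the arrays that the real one matches. Splits with at least as many genes as the real one numbered 10 for CR against AD (real 0, highest other 1), which a real count of 0 fixes in advance. That number was 1 for RFR against AD (real 2, highest other 0), for CR against RFR (2 and 1), amygdala against hypothalamus (3717 and 0), amygdala against prefrontal cortex (2815 and 0) and hypothalamus against prefrontal cortex (6053 and 0).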
